A study of Mus musculus with 12 samples.

How the data were processed

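RNA sequencing was analysed from 12 libraries of primary mouse embryonic fibroblasts on a hybrid 129/B6 background, wild type (WT) or knockout (KO) for the long noncoding RNA lincRNA-p21. Cells of each genotype were either mock treated or, per the labels' protocols, given 0.5 mM doxorubicin for 24 hours, which made 4 groups of 3 biological replicates. The unit of that dose is given as stated and is in doubt, since micromolar doses are more usual. Doxorubicin is an anthracycline that damages DNA and thereby activates p53. Per the labels' protocols, libraries came from a stranded mRNA kit. The submitters' processing notes name TopHat2 2.0.6, HTSeq, edgeR and the mouse assembly NCBIM37, and what each tool did was not used here.

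The values deposited by the authors were CPM (reads of a gene scaled to its library total) per gene, in 2 tables, each with 1 treatment and both genotypes. The mock table held 10648 genes and 11125 were in that of doxorubicin, of which 10292 were in both. Each library's values were multiples of 1 read over a single total, with 100% of values whole within 0.001 of a read, so no further scaling was visible and both tables shared a scale. The totals ran from 14327048 to 20511907 reads per library, and the listed genes held 99.2 to 99.6% of them. The 10 highest genes took 6.53 to 11.1% of the CPM of a library. Tests were run on CPM, the unit of the tables, and the totals served to describe depth.

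The gene selection was uneven between genotypes. Every listed gene lay above 2 CPM in all 3 WT libraries of its table, whereas 164 genes of the mock table and 313 of the doxorubicin table had a KO library at or under 2 CPM. Genes expressed in KO and low in WT were therefore not analysed here, which limits what can be seen to be higher in KO. Per the labels, the tables are marked as without chromosomes Y and X. The annotation match nonetheless placed 22 genes measured in mock and 24 measured after doxorubicin on chromosome X, and 0 on Y. LincRNA-p21 itself was not analysed here. Gene names were matched to a GRCm38 annotation, 9833 as symbols and 1215 as synonyms, with 433 not matched. Because the submitters' assembly differs, no coordinates are given and the annotation served only for names, chromosomes and the order of neighbouring genes.

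Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(CPM + 1), with Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. KO was compared with WT within each table. All 12 libraries in 4 groups were fitted for the genotype by treatment interaction and for doxorubicin against mock. The planned filter, a mean of at least 1 CPM, removed 0 genes. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 22 lists. The same lists were run with an estimated correlation and with fry, which asks whether the genes of a list move one way without comparing them with other genes. The 22 lists held 790 entries, of which 563 were matched. The tests intended for counts were not run, since the unit of the tables was CPM.

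The labels give WT and KO the same replicate numbers, so it was checked whether samples with the same number deviated together from their group means. Within the mock table the correlations of same-numbered WT and KO samples were 0.710 to 0.855 across genes, and within that of doxorubicin they were 0.669 to 0.800. For different numbers all were negative, at most -0.0668 in mock and -0.114 in doxorubicin. Deviations of the 3 libraries of a group sum to 0, which pushes these values below 0, so they are not separate evidence of pairing. Across treatments, samples of the same genotype and number correlated at 0.394 to 0.728. The pairing is thus taken from the data and the shared numbers; the labels do not say what a number stands for. A fit with the replicate number as a block was planned as the alternative, and its values stand beside the others where they change a call. With 3 pairs it rests on few residual degrees of freedom.

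On simulated data built from the mock libraries, the fit without a block called 1.49% of genes changed 1.5-fold, 47.8% of those changed 2-fold and 80.3% of those changed 4-fold, out of 10648 genes. With the block it called 100% at each size and 15 unchanged genes. On data built from the doxorubicin libraries, with 11125 genes, the corresponding shares without a block were 0, 32.8 and 93.9%. With the block they were 95.5, 100 and 100%, with 9 unchanged genes called. Beside counting noise, each simulated gene was given the same spread, the median over genes in the blocked fit. Real genes differ in spread, so these shares do not give the power for real genes and can overstate it.

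The lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule names lincRNA-p21, Cdkn1a, Trp53 and Mdm2, the 10 largest called changes each way that separate the groups and lie above the lowest 25% of genes by mean, the 5 smallest p-values each way where none is called, up to 4 members per described list and the 10 smallest interaction p-values. Its use on the blocked fit and on doxorubicin against mock was decided after the fit without a block made no genotype calls, and Hox genes outside the rule were chosen after their values were seen. Other settings tried were the pseudocount, a higher expression filter, quantile normalization, median centring, limma settings, thresholds, the block and leaving out each library. Leaving out a pair, combining the block with other settings and an interaction fit with a response for each number were added after the data were seen. A result that the rule would name was left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.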

Results

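Expression was measured in mouse embryonic fibroblasts of 4 groups, WT mock, KO mock, WT doxorubicin and KO doxorubicin, with 3 libraries in each. Library totals ran from 14327048 to 19956779 reads in WT mock, 15705627 to 19794115 in KO mock, 14406465 to 20511907 in WT doxorubicin and 15627903 to 20292279 in KO doxorubicin. The design asks what loss of lincRNA-p21 does to Cdkn1a, its neighbour on chromosome 17, to Polycomb target genes and to cell cycle genes, with and without DNA damage. The targeted RNA was not analysed here, so the genotype labels were not checked against it.

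Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, was at 566 ± 54.7 CPM in WT mock and 315 ± 38.1 CPM in KO mock cells (SD, n = 3 each). The difference was -0.85 on the log2 scale (SE 0.12), and every KO library lay below every WT library. Such a separation, in either direction, held for 9.98% of genes in mock, against 10% by chance. Over all genes Cdkn1a did not pass without the block (limma, adjusted p = 0.395), whereas it fell with the replicate block (adjusted p = 0.0223). After doxorubicin, Cdkn1a was at 1260 ± 175 CPM in WT and 1078 ± 21.9 CPM in KO cells, a log2 difference of -0.22 (SE 0.15, adjusted p = 0.513, and 0.143 with the block). Trp53, which encodes p53, and Mdm2, its ubiquitin ligase, did not pass in either table. In mock cells Trp53 was at 124 CPM in WT and 143 CPM in KO (log2 difference 0.19, SE 0.14), and Mdm2 at 252 ± 20.8 and 251 ± 33.7 CPM. After doxorubicin Trp53 was at 283 ± 59.2 CPM in WT and 220 ± 42.0 CPM in KO, and Mdm2 at 875 ± 107 and 928 ± 3.33 CPM.

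**Figure D1:**
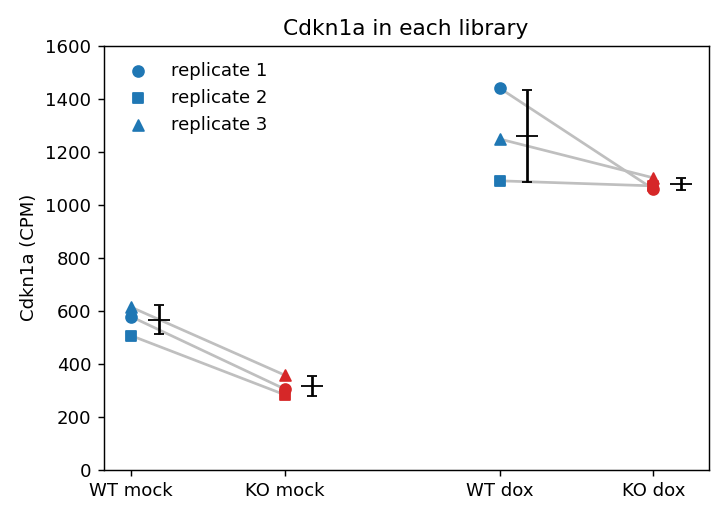
Cdkn1a in each library, in CPM, by group, with lines joining WT and KO libraries of the same replicate number and bars giving mean ± SD (n = 3). The KO mock libraries lie between 283 and 357 CPM and the WT mock libraries between 506 and 613 CPM, whereas the doxorubicin groups overlap, with KO at 1059 to 1102 CPM and WT at 1091 to 1440.3 CPM.

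In mock cells, Hoxd13, Hoxa13 and Tbx4 were among the genes higher in KO and C1qtnf3 among those lower, in calls made with the replicate block. Hoxd13 rose from 12.4 ± 3.58 to 36.5 ± 3.50 CPM (log2 1.52, adjusted p = 0.0246 with the block), Hoxa13 from 2.74 ± 0.145 to 8.13 ± 1.14 CPM (log2 1.28, adjusted p = 0.0246) and Tbx4, a hindlimb transcription factor, from 3.70 ± 0.896 to 14.3 ± 4.65 CPM (log2 1.68, adjusted p = 0.0302). Nt5e, an ecto-5'-nucleotidase, rose by log2 1.81, the gap junction gene Gjb2 by 1.72, the IL-33 receptor gene Il1rl1 by 1.59 and the imprinted zinc finger gene Plagl1 by 1.03, and Mecom, a transcription factor gene, by 0.74. Itih2, Scara3, Glis3, the syndecan gene Sdc4 and the adaptor gene Pag1 also rose, by log2 0.81 to 1.14. C1qtnf3 fell by 1.18 on the log2 scale, and Mrvi1, Megf10, Kcnab1, Tfpi, Ptprz1 and Gsto1 fell by 0.45 to 0.93. Without the block, limma called 0 of 10648 genes, with 440 at an unadjusted p under 0.05 and a smallest adjusted p of 0.199. With the block it called 98, 60 higher and 38 lower (51 and 53 with quantile normalization), and that count was 4, 0 or 2438 when pair 1, 2 or 3 was left out.

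Contractile genes of myofibroblasts and smooth muscle were lower in KO mock cells, with 16 of 18 measured members below WT and a median log2 difference of -0.40. The list was called by camera (adjusted p = 3.27e-10), but not with an estimated correlation (adjusted p = 0.515 with an estimated correlation). With the block 5 members fell over all genes and 13 when adjusted over the list alone. Among them, Mylk, the myosin light chain kinase gene, fell from 33.8 ± 3.65 to 20.3 ± 2.95 CPM and Myl9, a regulatory myosin light chain gene, from 753 ± 115 to 514 ± 46.0 CPM. Without the block 0 members passed over all genes and 1 when adjusted over the list alone.

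Genes of mitosis were higher in KO mock cells, with 57 of 57 G2/M members above WT, a median of 0.44 and a camera adjusted p of 1.95e-13 (adjusted p = 0.533 with an estimated correlation). Without the block 0 members passed, over all genes or adjusted over the list alone. With the block 6 rose over all genes and 54 adjusted over the list alone, among them Prc1, a spindle midzone gene (67.3 ± 13.6 to 102 ± 28.8 CPM), and the condensin gene Smc4 (102 ± 19.1 to 146 ± 34.2 CPM). Of the genes of S-phase entry and replication, 54 of 55 were above WT, with a median of 0.29 and a camera adjusted p of 1.61e-06 (adjusted p = 0.648 with an estimated correlation, and not called without KO mock replicate 2, adjusted p = 0.535). With the block 0 of these passed over all genes and 30 adjusted over the list alone. Ribosomal protein genes, a sign of growth state and of RNA quality, were above WT in 43 of 43 members, with a median of 0.12 (adjusted p = 0.000704, and adjusted p = 0.648 with an estimated correlation). That call was lost without WT mock replicate 3, KO mock replicate 1 or KO mock replicate 2 (adjusted p = 0.0880, 0.0888 and 0.152). Over all genes 7094 of 10648 lay above WT, with a median of 0.058. Median centring brought the ribosomal median to 0.057, with 42 of 43 above WT. Camera called 8 of the 22 lists, and 2 other splits of the same 6 libraries, which do not keep the pairs, also gave 8.

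Interferon-stimulated genes were below WT in 21 of 21 members, with a median of -0.81 and a camera adjusted p of 2.36e-12 (adjusted p = 0.532 with an estimated correlation). No member passed with or without the block. The pairs differed, with medians of -1.56, -1.22 and 0.34. Fibroblast and matrix genes had a median of -0.13 (adjusted p = 6.16e-06, and adjusted p = 0.533 with an estimated correlation). That call was lost with quantile normalization (adjusted p = 0.350) and without KO mock replicate 2 (0.219). With the block 1 member rose and 1 fell over all genes, and 1 rose and 7 fell adjusted over the list alone. The riser was Mmp2, a gelatinase gene (359 ± 83.3 to 523 ± 67.6 CPM), and the other was S100a4, a calcium-binding protein gene named after its values were seen (345 ± 150 to 245 ± 115 CPM). Skeletal muscle markers (3 measured, median -0.32, adjusted p = 0.00693, and adjusted p = 0.515 with an estimated correlation) and endothelial markers (6 measured, median -0.23, adjusted p = 0.0279, and adjusted p = 0.515 with an estimated correlation) were also lower. The muscle call was lost with quantile normalization (adjusted p = 0.169) and without WT mock replicate 2, KO mock replicate 1 or KO mock replicate 3 (0.180, 0.0618 and 0.126). The endothelial call was lost with quantile normalization (0.195) and without WT mock replicate 1, WT mock replicate 3 or KO mock replicate 1 (0.0684, 0.0858 and 0.104). Acta1, the skeletal actin gene, and Eng, an endothelial co-receptor gene, fell with the block, by 1.20 and 0.57 on the log2 scale. Only 3 of 28 muscle and 6 of 19 endothelial entries were measured, and the gene selection by WT values can leave out markers higher in KO.

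Polycomb targets, the developmental regulators that PRC2 classically marks, were not called as a list in mock cells. Of 52 measured, 24 were above and 28 below WT, with a median of -0.03, a mean of 0.09 and a camera adjusted p of 0.480. Without the block 0 passed over all genes, and 4 rose and 0 fell adjusted over the list alone. With the block 5 rose and 0 fell over all genes, and 7 rose and 3 fell adjusted over the list alone. A form of fry that counts changes in either direction gave the list an adjusted p of 0.00245 without the block. The cell cycle inhibitors and RB family had 0.0124 and every other list 0.71 or more. With the block the Polycomb value was 0.00749, but most lists passed there. After doxorubicin the Polycomb value was 0.155 without the block and 0.00974 with it. The p53 targets were not called (40 measured, median 0.07, camera direction down, adjusted p = 0.602), and with the block Cdkn1a alone of them passed over all genes. Components of PRC1 and PRC2, the cell cycle inhibitors and RB family, and the neighbours of Cdkn1a had medians of 0.09, 0.09 and 0.01 and were not called by camera, whereas fry called the PRC1 and PRC2 list without the block (adjusted p = 0.0254) but not with it (0.0543). The median of the neighbours turned to -0.05 with quantile normalization or median centring, which also brought the neural and immediate-early medians below 0. Nor were imprinted genes (-0.02), secreted inflammatory factors (-0.05), immediate-early genes (0.02), cholesterol synthesis genes (0.08), or markers of neural (0.03), blood (0.29), epithelial (-0.21), cartilage and bone (0.30) or adipocyte (0.09) cells.

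Hox genes, which pattern the body axis, were set out by paralog group, without a test between groups. In mock cells, of groups 11 to 13, 4 of 4 measured genes lay above WT (median 1.12), and 3 rose with the block, Hoxa11, Hoxa13 and Hoxd13. Of groups 1 to 8, 15 of 16 lay below WT (median -0.27, and all 16 with quantile normalization or median centring), and 0 were called with or without the block. Of groups 9 to 10, 2 of 6 lay above WT (median -0.11) and 0 were called. After doxorubicin, groups 11 to 13 had a median of 0.48, with Hoxa13 and Hoxd13 higher and Hoxc13 lower with the block, and groups 1 to 8 had a median of -0.16, with Hoxc5 and Hoxc6 lower. Groups 9 to 10 then had a median of -0.23, with Hoxa9 and Hoxa10 higher with the block and Hoxc10 lower, from 30.2 ± 8.47 to 13.9 ± 4.44 CPM (log2 -1.08, adjusted p = 0.0044 with the block). By cluster, every measured Hoxc gene lay below WT in both treatments. The differences ran from log2 -0.25 (Hoxc9) to -0.61 (Hoxc5) in mock and from -0.13 (Hoxc8) to -1.08 (Hoxc10) after doxorubicin. In mock every measured Hoxb gene lay below WT too. After doxorubicin the blocked calls lower were all Hoxc genes, and those higher were Hoxa or Hoxd genes. Hoxc13 was not measured in mock. Both groupings were made after the values were seen.

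**Figure D2:**
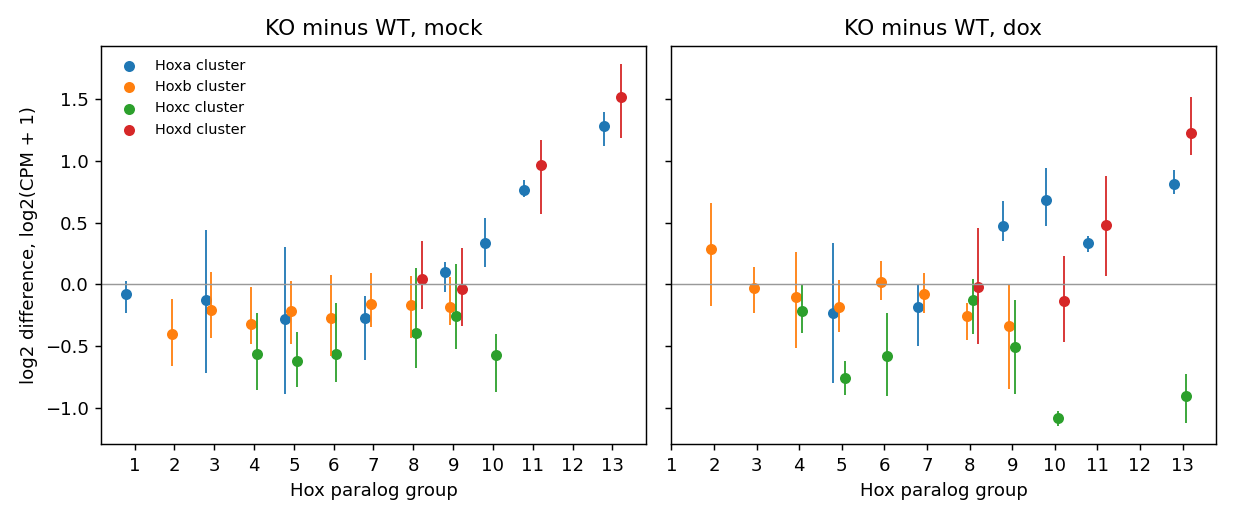
Log2 difference between KO and WT of each measured Hox gene against its paralog group, in mock cells (left) and after doxorubicin (right), coloured by cluster, with points giving the mean difference and lines the range over 3 pairs. Hoxd13 lies at 1.52 in mock and 1.22 after doxorubicin, and Hoxc13 at -0.90 after doxorubicin.

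After doxorubicin, Enpp2, Hmga2 and Hoxd13 were among the genes higher in KO, and Ifi202b and Des among those lower, again in calls made with the block. Enpp2, the lysophospholipase autotaxin, rose from 11.0 ± 3.90 to 65.8 ± 19.6 CPM (log2 2.48, adjusted p = 0.00085 with the block). Hmga2, a chromatin protein gene of growing embryonic cells, rose by log2 1.00, from 381 ± 41.0 to 765 ± 81.7 CPM, and Hoxd13, Tbx4 and Foxc2 rose by 1.22, 1.51 and 1.07. The collagen gene Col11a1 rose by 0.92. Nt5e, the osteoclast cytokine gene Tnfsf11, Fhdc1, Ccbe1, Robo2 and Ahrr rose by log2 1.04 to 1.55. The interferon-inducible gene Ifi202b fell by 3.02 on the log2 scale, from 38.5 ± 25.7 to 3.04 ± 1.59 CPM. Des, which encodes desmin, fell by 1.41, and C1qtnf3, Lrp2, Rtn4rl1, Adcy5, Scn4b, Frzb, Mmp17 and Cited4 fell by 1.20 to 1.62. Slc4a8, Ifi27l2b and Lrrc15 fell by 1.13, 1.40 and 0.89. Without the block limma called 0 of 11125 genes, with 1246 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0963. With the block it called 2820, 1311 higher and 1509 lower. Among the 10292 genes in both tables these calls were 1286 higher and 1179 lower, so the balance turned with the set of genes. The gene selection by WT values can leave out genes higher in KO, so the balance of higher and lower calls is not free of it. Its part was not tested. A blocked fit of all 12 samples, limited to those 10292 genes, called 2117 higher and 1509 lower. Without pair 1, 2 or 3 the blocked fit of the 11125 genes called 692 (180 higher and 512 lower), 2590 (1108 and 1482) or 1560 (538 and 1022).

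Mitotic genes were lower in KO than in WT after doxorubicin, with 40 of 45 G2/M members below WT, a median of -0.44 and a camera adjusted p of 0.000104 (adjusted p = 0.909 with an estimated correlation). With the block 16 fell and 0 rose over all genes, and 17 fell and 1 rose adjusted over the list alone. Ccnb1, which encodes cyclin B1, fell from 24.3 ± 10.1 to 11.4 ± 3.93 CPM and the kinetochore gene Spc25 from 50.3 ± 13.2 to 31.1 ± 12.4 CPM. The replication list had a median of -0.30 (adjusted p = 0.0117, and adjusted p = 0.909 with an estimated correlation), and with the block 14 members fell and 2 rose, with Mcm7, a replicative helicase gene, at 120 ± 21.5 in WT and 84.4 ± 16.1 CPM in KO. Without WT dox replicate 2 neither list was called (adjusted p = 0.844 for G2/M and 0.926 for replication). The replication call was also lost without KO dox replicate 3 (0.120) and, with the block, without pair 2 (0.0871), where G2/M passed (0.0191). Pair 1 had a G2/M median of -0.05, against -0.92 and -0.37 in the other pairs.

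Ribosomal protein genes were above WT in 42 of 43 members after doxorubicin, with a median of 0.21 (adjusted p = 4.14e-05, and adjusted p = 0.909 with an estimated correlation). With the block 17 of them rose and 0 fell. Adipocyte markers were below WT in 6 of 6, with a median of -0.97 (camera adjusted p = 0.0167, and adjusted p = 0.563 with an estimated correlation), and 4 fell with the block, among them Cebpa, a regulator of fat cell differentiation (82.9 ± 26.4 to 43.0 ± 13.9 CPM). Epithelial markers were below in 8 of 9, with a median of -0.52 (adjusted p = 0.0167, and adjusted p = 0.563 with an estimated correlation). Of these 5 fell with the block, including the splicing regulator gene Esrp2, from 71.4 ± 11.6 to 31.6 ± 6.89 CPM. Only 6 of 18 adipocyte and 9 of 24 epithelial entries were measured. The gene selection by WT values can leave out markers higher in KO, and its part in these 2 results was not tested. The adipocyte call was lost without WT dox replicate 2 or KO dox replicate 3 (adjusted p = 0.107 and 0.0563), and the epithelial call without WT dox replicate 1, WT dox replicate 2 or KO dox replicate 3 (0.0900, 0.0655 and 0.133). The number of called lists was 5, against up to 14 in other splits of the same 6 libraries, which do not keep the pairs. It was 1 without WT dox replicate 2, 2 without KO dox replicate 3 and 9 without WT dox replicate 3 or KO dox replicate 2.

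Polycomb targets and p53 targets were not called as lists in KO against WT after doxorubicin. Of 59 Polycomb targets, 14 rose and 12 fell with the block, or 17 and 13 adjusted over the list alone, against 4 and 0 adjusted over the list alone without it (median -0.05, camera adjusted p = 0.913). Of 39 p53 targets, 3 rose and 5 fell with the block (median 0.04, mean -0.04, camera adjusted p = 0.662). Among them Phlda3, an inhibitor of Akt, rose by log2 0.42, whereas Fdxr, which encodes ferredoxin reductase, fell by 0.97 and Sesn1, a sestrin gene, by 0.53. The p53 target median turned to -0.01 with median centring. Over all 11125 genes, 1311 rose and 1509 fell with the block.

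**Figure D3:**
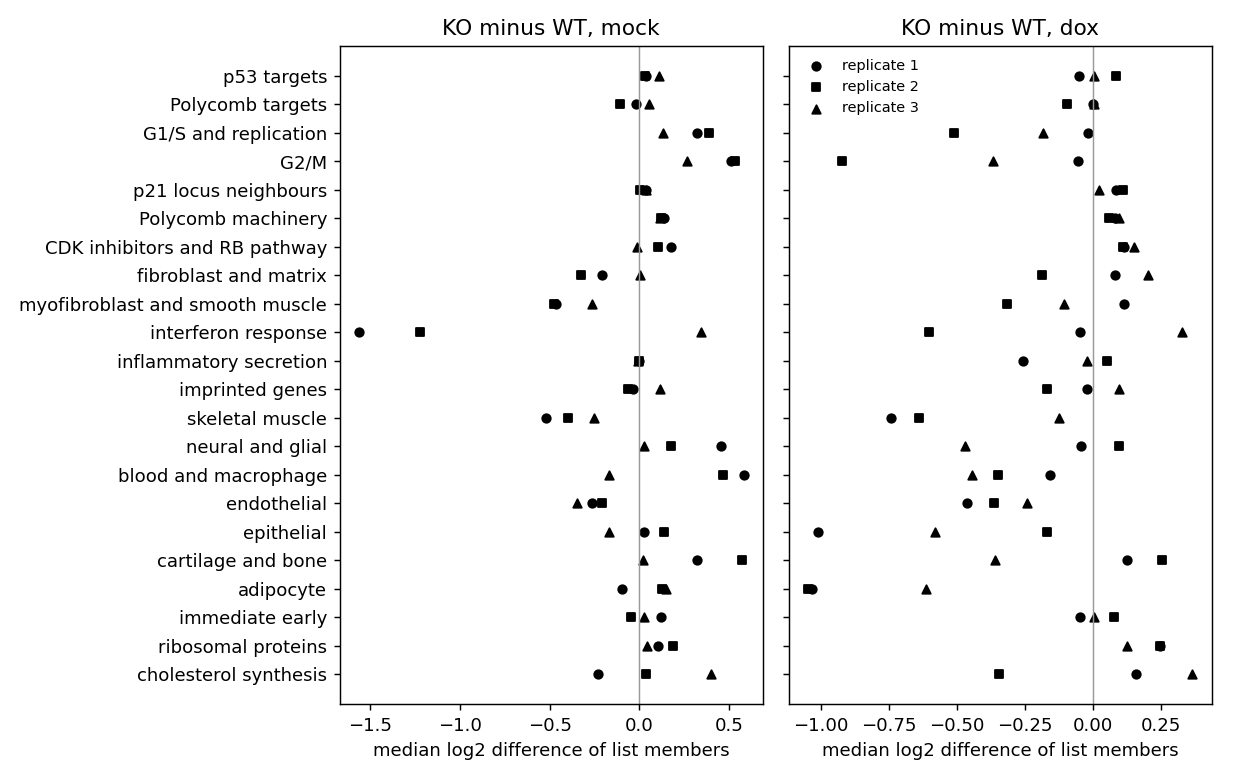
Median log2 difference between KO and WT over the members of each gene list, for each replicate number, in mock cells (left) and after doxorubicin (right). The G2/M medians are 0.51, 0.54 and 0.27 in mock pairs 1 to 3 and -0.05, -0.92 and -0.37 after doxorubicin.

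Doxorubicin moved p53 targets up and cell cycle genes down in both genotypes. Against mock, limma without the block called 4863 of 10292 genes in WT cells, 2664 higher and 2199 lower, and 3552 in KO cells, 2052 higher and 1500 lower. Cdkn1a rose from 566 ± 54.7 to 1260 ± 175 CPM in WT (log2 1.15, SE 0.13, adjusted p = 6.93e-05) and from 315 ± 38.1 to 1078 ± 21.9 CPM in KO (log2 1.78, SE 0.13, adjusted p = 1.99e-05). Mdm2 rose by log2 1.79 in WT and 1.89 in KO, and Trp53 by 1.17 and 0.61. Of 39 p53 targets, 31 rose and 0 fell in each genotype, with medians of 1.00 in WT and 1.07 in KO (camera adjusted p = 2.34e-10 and 9.89e-13, and adjusted p = 0.396 and 0.265 with an estimated correlation). Adjusted over the list alone, 31 rose in WT and 34 in KO.

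Mitotic genes fell after doxorubicin in both genotypes, 33 of 45 in WT with 5 higher (median -1.56) and 39 of 45 in KO with 3 higher (median -2.48), with camera adjusted p of 9.84e-07 and 7.23e-17 (adjusted p = 0.674 and 0.351 with an estimated correlation). Top2a, the topoisomerase that doxorubicin poisons, fell from 165 ± 38.7 to 13.8 ± 11.4 CPM in WT and from 228 ± 71.5 to 14.7 ± 7.87 CPM in KO. Gtse1, a p53-regulating gene of the G2/M list, rose in WT, from 69.6 ± 3.63 to 177 ± 23.5 CPM. In mock 57 G2/M and 55 replication members were measured, of which 45 and 48 could be compared here. Every listed gene lay above 2 CPM in all 3 WT libraries, so members that fell lowest in WT were not analysed. This can make the fall look smaller in WT than in KO, and its part in the medians was not tested. Of the 48 replication genes, 26 fell and 6 rose in WT (median -0.77) and 36 fell and 2 rose in KO (median -1.34), with adjusted p of 1.67e-05 and 2.6e-14 (adjusted p = 0.674 and 0.351 with an estimated correlation), and the polymerase gene Pole had log2 changes of -2.05 and -2.51.

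Of the cholesterol synthesis genes, 15 of 18 fell in WT and 16 in KO (medians -1.40 and -1.58, adjusted p = 4.41e-07 and 1.62e-10, and adjusted p = 0.555 and 0.351 with an estimated correlation), among them Insig1, a sterol sensor gene, from 127 ± 24.9 to 22.2 ± 4.84 CPM in WT. Fibroblast and matrix genes fell in 18 of 36 members in WT and 15 in KO (medians -0.87 and -0.83, adjusted p = 1.02e-05 and 5.75e-06, and adjusted p = 0.555 and 0.392 with an estimated correlation), with Pdgfrb, a growth factor receptor gene, at 605 ± 71.8 and 101 ± 27.9 CPM in WT mock and WT doxorubicin. Myofibroblast genes fell in 9 of 18 members in WT, where 1 rose, and 5 in KO, where 0 did (adjusted p = 0.00278 and 0.0123, and adjusted p = 0.673 and 0.634 with an estimated correlation), among them the smooth muscle myosin gene Myh11, with log2 changes of -3.31 and -3.53. Ribosomal protein genes fell in 16 of 43 members in WT and 8 in KO, with 1 higher in each (adjusted p = 0.00278 and 0.0119, and adjusted p = 0.727 and 0.804 with an estimated correlation), with Rpl3 at -0.97 and -0.71. In KO the myofibroblast call was lost without KO mock replicate 2 (adjusted p = 0.0601) and the ribosomal call without KO dox replicate 3 (0.0783).

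The largest rises in both genotypes included Sbsn, which encodes suprabasin, by log2 6.04 in WT (to 243 ± 122 CPM) and 5.27 in KO, and the transporter gene Slc4a11, at 3.78 ± 0.994 and 276 ± 66.4 CPM. Icam1, an adhesion molecule gene, rose by log2 5.23 in WT and 4.03 in KO, and Perp, a p53 target of cell adhesion, by 4.92 and 3.88. Immediate-early genes rose in 11 of 21 members in WT and 12 in KO, with 1 lower in each (adjusted p = 0.0182 and 0.0123, and adjusted p = 0.555 and 0.375 with an estimated correlation), with Fos at log2 2.82 and 1.92. Interferon-stimulated genes rose in 6 of 20 members in WT and 14 in KO (medians 1.13 and 1.87, adjusted p = 0.0463 and 1.44e-05, and adjusted p = 0.819 and 0.570 with an estimated correlation). The KO call was kept in 17 of 17 settings and the WT call in 9 of 17. The latter was lost with the block without pair 3 (0.140), and without WT mock replicate 2 or 3 (0.101 and 0.377), WT dox replicate 1, 2 or 3 (0.0915, 0.0628 and 0.0514) or KO dox replicate 1 or 3 (0.0540 and 0.0501). Epithelial markers rose in 2 of 5 members in WT and 3 in KO (adjusted p = 0.0385 and 0.0197, and adjusted p = 0.555 and 0.351 with an estimated correlation), and the WT call was lost without WT mock replicate 3, WT dox replicate 1 or WT dox replicate 2 (0.0581, 0.0685 and 0.0569).

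**Figure D4:**
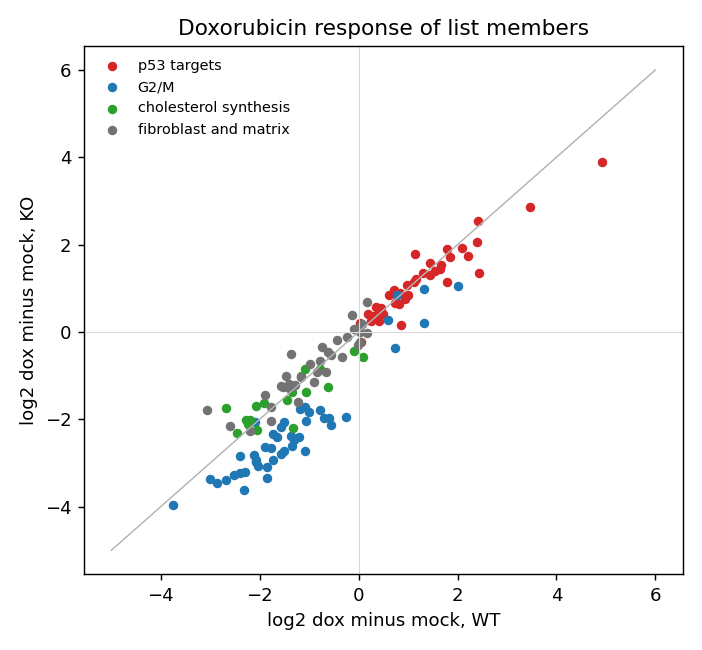
Log2 change with doxorubicin in KO (vertical) against WT (horizontal) for members of 4 gene lists, each point a gene, with the diagonal marking equal change. Across the 10292 genes the changes in the 2 genotypes correlated at 0.923, which is a correlation across genes and not across independent replicates.

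No gene passed the genotype by treatment interaction, which asks whether the KO difference itself differed between mock and doxorubicin. Limma called 0 of 10292 genes without the block, with 468 at an unadjusted p under 0.05, and 0 with genotype and replicate number together as a block. A fit with a doxorubicin response of its own for each replicate number, added after the data were seen, called 1332. For Cdkn1a the difference between the log2 differences was 0.63 (SE 0.18, adjusted p = 0.922), and adjusted p = 0.00497 in the added fit. Camera called 3 lists, G2/M (median -0.90, adjusted p = 2.09e-14), replication (-0.48, adjusted p = 3.23e-09) and interferon (0.71, adjusted p = 0.000153), each with adjusted p = 0.881 with an estimated correlation. The interferon call was lost without WT mock replicate 1 (adjusted p = 0.486). Reassigning genotype within each treatment, without keeping the pairs, gave at least as many called lists in 92 of 100 draws, and the added fit called 6 lists. The gene selection by WT values can leave out G2/M and replication members that fell lowest in WT, and its part here was not tested. In the fit without the block, where none passed, genes with the smallest p included the intermediate filament gene Synm (4.36, 8.80, 56.2 and 39.3 CPM in WT mock, KO mock, WT doxorubicin and KO doxorubicin), Celsr2, Gdnf, Chfr, St3gal5, Angpt4, Wdtc1, Abhd6 and Lrch1.

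Genes on chromosome 17, which carries lincRNA-p21, were not enriched among the blocked calls. Of 95 blocked mock calls with a known chromosome 2 lay there (2.11%, against 4.95% of genes tested, two-sided Fisher's exact test p = 0.334), and of 2742 blocked doxorubicin calls 118 did (4.30% against 4.86%, p = 0.123). In the order of the GRCm38 annotation, of the 20 tested genes on each side of Cdkn1a 0 were called in mock and 11 after doxorubicin with the block. Those 11 of 40 genes are a similar share to the 2742 called of all 10724 genes with a known chromosome. In mock 95 of 10305 such genes were called.

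Calls made with the block in the 2 tables overlapped, with 28 genes higher in both, against 7.37 for independent lists of that size, and 24 lower in both, against 4.24. With genotypes exchanged within a pair, limma with the block called 0 genes in each table, so no overlap could be counted there. The KO differences correlated at 0.365 across genes between the tables. A deviation common to the WT and KO samples of a number cancels in KO minus WT. One shared by the mock and doxorubicin samples of the same genotype and number does not, so the tables cannot be taken as independent. Such an overlap or correlation can therefore arise without a genotype effect. For the correlation, exchanging the genotypes within pair 1, 2 or 3 of both tables gave 0.157, 0.255 or 0.456.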

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

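The 3 list results here were found by a test of the difference between treatments. The tests with swaps of genotype within pairs and the fits that leave out a pair were chosen only after the results were seen; the other splits and the other tests on the G2/M list were written down beforehand. How a G2/M test within pairs was read was settled after its value was seen, and an earlier reading, by which every pair had to pass its own standard error, left that explanation open.

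The KO minus WT difference of the G2/M list was lower after doxorubicin than in mock cells by a median of -0.90 (limma camera, adjusted p = 2.09e-14), and that of the G1/S and replication list by -0.48 (adjusted p = 3.23e-09). That of the interferon response list was higher by 0.714 (adjusted p = 0.000153). Each had an adjusted p of 0.881 with an estimated correlation, and 0 single genes passed with limma, against 468 at an unadjusted p under 0.05. When genotype was reassigned within each treatment, 92 of 100 draws gave at least the real 3 called lists, with up to 12, so chance cannot be excluded for the list count by these draws, which do not keep the pairs. The draws are uninformative for genes, since a real count of 0 is reached by all 100, with up to 14. The gene selection by WT values can leave out G2/M and replication members that fell lowest in WT. Its part in these differences between treatments was not tested. The interferon call was lost without WT mock replicate 1 (adjusted p = 0.486). The fit with a response for each number called 1332 genes and 6 lists, and its other swaps gave 0 genes (1 of 4 swaps) and at most 6 lists (3 of 4 swaps), too few for a share under 0.05.

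The G2/M genes were lower in KO after doxorubicin. The uneven gene selection, which could hide members low in WT, would need well-expressed members at or above 0. The 13 members with a mean of at least 20 CPM instead had a median of -0.413, below 0 by more than 2 standard errors over members. That error treats the members as independent, whereas the estimated correlation within the list was 0.531. It does not cover spread between cultures, so it understates the uncertainty. A single pair as the carrier would leave the other pairs at or above 0. The medians of all 3 pairs lay below 0, 2 of them beyond 2 standard errors over members (-0.92 and -0.37), whereas pair 1 was at -0.05 (standard error 0.0868). These errors describe spread over genes within 1 pair of cultures and not between cultures. They show a lower list in 2 pairs but cannot say whether other cultures would repeat it. With the block camera called the list whichever pair was left out (adjusted p = 0.0191 without pair 2). The blocked call over all pairs was lost with an estimated correlation (adjusted p = 0.795), and fry did not call the list (0.416). Without the block, WT dox replicate 2 was needed for the call (adjusted p = 0.844 without it). A different response of the KO cells to damage stays open.

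The numbers of called lists and genes were set against other groupings of the same libraries. The 10 splits of 6 libraries, and the 4 swaps within pairs, are too few for a share under 0.05. Splits other than the real one also do not keep the replicate numbers balanced, so differences between numbers can add to their counts. In mock cells 8 lists were called and at most 8 in another split (3 of 10 splits gave as many), and with the block 8 against at most 9 (2 of 4 swaps). After doxorubicin 5 lists were called against at most 14 (8 of 10 splits), and with the block 6 against at most 11 (3 of 4 swaps). For genes without the block, the real split and the highest other both gave 0 in each table (10 of 10 splits). With the block the real grouping gave 98 in mock and 2820 after doxorubicin, and the other swaps 0 (1 of 4 in each). For doxorubicin against mock within 1 genotype, the real split gave 4230 genes in WT and 3191 in KO and the others 0 (1 of 10 in each).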

How the results depend on the processing

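The alternatives that leave out a pair, that join the block with another setting, and the interaction fit with a response for each number were chosen after the data were seen. The cause was not tested for any change below except where fewer samples were fitted.

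With the replicate block, KO against WT called 98 genes in mock (against 0) and 2820 after doxorubicin (against 0), and Cdkn1a in mock passed at -0.85 (adjusted p = 0.0223). With the block in a fit of all 12 samples, limited to the 10292 genes in both tables, these were 140, 3626 and -0.85. With the block and quantile normalization they were 104, 2602 and -0.85, and with a mean of at least 5 CPM 76, 2703 and -0.85. Without pair 1, 2 or 3 the blocked counts were 4, 0 and 2438 in mock and 692, 2590 and 1560 after doxorubicin, and Cdkn1a passed at -0.88 without pair 3. The interaction with a response for each number called 1332 genes (against 0) and 6 lists (against 3). The block gave 5 interaction lists, adding the myofibroblast (adjusted p = 0.0340) and ribosomal protein lists (0.0483), and after doxorubicin it added the skeletal muscle list (0.0371), all lost with an estimated correlation (0.485, 0.727 and 0.795). Beside these and the genes whose blocked values the report gives, it changed no other camera call.

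Without the block, mock calls rose from 0 to 1 without trend and to 5 in a fit of all 12 samples. Doxorubicin calls rose from 0 to 2 at a threshold of 0.1, to 1 with pseudocount 0.1 and to 2 in a fit of all 12 samples. An estimated correlation called 0 lists in each of the 5 comparisons. Fry called 1 list in mock (PRC1 and PRC2 components, adjusted p = 0.0254), 1 after doxorubicin (endothelial, 0.0184), 0 for the interaction, and 16 and 10 for doxorubicin against mock in WT and KO. With the block both genotype calls were lost (0.0543 and 0.0723), skeletal muscle was called in mock (0.000713), and the other counts were 0, 17 and 20. Quantile normalization gave 5 lists in mock, and pseudocount 5 gave 5 for the interaction. The correlation of the KO differences across genes was 0.391 with pseudocount 0.1, against 0.365.

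Leaving out a library in turn gave 0 to 0 genes for KO against WT in mock, after doxorubicin and for the interaction. It gave 3870 to 4839 genes for doxorubicin against mock in WT and 2546 to 3699 in KO. Called lists ranged from 5 to 9 in mock (5 without KO mock replicate 1), from 1 to 9 after doxorubicin (1 without WT dox replicate 2, 2 without KO dox replicate 3, 9 without WT dox replicate 3 or KO dox replicate 2), from 2 to 7 for the interaction (7 without WT dox replicate 2), from 8 to 10 in WT and from 9 to 10 in KO. The Cdkn1a difference ranged from -0.94 to -0.77 in mock and from -0.32 to -0.12 after doxorubicin. With the block, leaving out a pair gave -0.88 to -0.81 and -0.31 to -0.10, 7 to 10 lists in mock, 4 to 7 after doxorubicin, 9 to 10 and 10 to 10 for doxorubicin against mock in WT and KO, and 4769 to 5369 and 2916 to 4187 genes.

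Genes not called changed sign with fewer samples. Mdm2 in mock ranged from -0.0999 (without KO mock replicate 2) to 0.0943 (without KO mock replicate 3), with 0.0570 without WT mock replicate 2 and 0.0450 with the block without pair 3. After doxorubicin it ranged from -0.0113 (without WT dox replicate 2) to 0.158 (without WT dox replicate 3), with -0.0141 with the block without pair 2. In mock, Tnnt2 ranged from -0.722 (without KO mock replicate 2) to 0.221 (without KO mock replicate 1), and Egfl7 from -0.0281 (without KO mock replicate 1) to 0.409 (without WT mock replicate 1). Both also changed sign without WT mock replicate 2, to 0.200 and -0.0244. Of the named genes' values for doxorubicin against mock, 0 of 1122 in WT and 0 of 1105 in KO reversed, 11 and 20 lost their call and 7 and 3 gained one. The planned tests for counts were not run, and the alternative without a filter gave the main values, since the filter removed 0 genes.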

Other observations

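Hoxa13, Hoxd13 and Tbx4, genes of the posterior body and hindlimb, were higher in KO than in WT in each of the 3 pairs of both tables. Not every posterior gene was, since Hoxc10 and Hoxc13 were lower in each pair after doxorubicin (log2 -1.08 and -0.90, adjusted p = 0.0044 and 0.00713 with the block). The mean differences of the other measured Hoxc genes also lay below WT there. In mock those of every measured Hoxc gene did, and Hoxc13 was not measured. Pitx1, a hindlimb gene upstream of Tbx4, was not called, at log2 0.78 in mock and 0.72 after doxorubicin. The tests on transcripts with clone names and on Polycomb targets low in WT were chosen only after the result was seen. The bounds first written for the region and Polycomb tests counted a median within its own error as evidence against, which such a median cannot give. After the values were seen, the region test was read as asking for a median beyond 2 standard errors of 0, and the Polycomb test as asking whether the median came within 2 standard errors of the change to be explained. The Polycomb reading was changed several times, and the one before it left that explanation open.

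Cells from another body region in the KO samples may account for the posterior genes that were higher. Other posterior and hindlimb genes, listed before this test, had a median log2 difference of 0.334 in mock (standard error 0.218, 9 genes) and 0.181 after doxorubicin (0.347, 12 genes), too wide to decide. A general release of Polycomb targets as large as the posterior rise would move the listed targets by about as much as Tbx4 and Hox groups 11 to 13. The medians of those genes were 1.28 and 0.65, and they were chosen after their values were seen. Members of that list outside the Hox clusters had medians of 0.0434 (0.117, 30 genes) and -0.0259 (0.118, 38 genes). Those no higher in WT than the highest of the posterior genes had medians of 0.28 (0.227, 13 genes) and 0.02 (0.171, 19 genes). Tbx4 is itself a member of both sets. The values argue only against a general release of that size among the measured targets. Targets at or under 2 CPM in WT were not analysed here, and a smaller general release, or a release of some targets only, stays open. An effect of the knockout on these genes stays open too.

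RP23-73N16.5 and AC145168.1, transcripts with clone names, were near 0 in every KO library. RP23-73N16.5 was at 1.38% of WT in mock (exact Clopper-Pearson 95% interval 0.166 to 5.09%) and 1.26% after doxorubicin (0.341 to 3.26%). AC145168.1 was at 3.54% (1.75 to 6.43%) and 4.27% (2.10 to 7.77%). The intervals cover counting error only. Deletion of the targeted locus is a candidate explanation, with 2 genes under 10% of the WT mean in every KO library of both tables, or 1 under 10% of the lowest WT library, the criterion used first. Their names were not matched to the annotation, so their position was not tested.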
